A study of Mus musculus with 10 samples.

How the data were processed

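RNA sequencing was analysed for 10 mouse libraries in 5 groups of 2. Per the labels' protocols, RNA was taken with a miRNeasy kit and 500 ng of total RNA went into stranded total RNA libraries. Femoral B cells were lysed without culture. Spleen cells without CD43, a surface protein that resting B cells lack, were cultured for 48 h with lipopolysaccharide (LPS, 5 µg/ml). The growth protocol adds interleukin 4 (IL4, 20 ng/ml), which the series' design text leaves out. SAHA (vorinostat), an inhibitor of histone deacetylases, is given as 200 nM in the sample names and as 200 ng/ml in the treatment protocol. The design text speaks of RNA pools, of 3 samples each in the spleen, where the sample names give 2 numbers per pool (4_et_7 and 6_et_8). The RAG2_deficient replicates are numbered 1 and 2 in the titles, as used here, and 2 and 3 in the descriptions. The p-values measure the spread between these pools only.

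The authors deposited 1 table of raw read counts per gene, with 46959 gene entries and 100 entries for spiked-in control sequences. Per the submitters' processing notes, reads were aligned with STAR 2.4.0a and counted with featureCounts from Subread 1.4.6-p1 on the mm10/GRCm38 genome. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of immunoglobulin V segments, histone genes, pseudogenes, gene families and overlapping or antisense genes are therefore uncertain gene by gene, because reads may be shared among near-identical copies. Gene coordinates come from the deposited table. Gene types come from GENCODE vM21, in which 44145 symbols were matched. Control sequences stayed out of library sizes and tests.

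The table names its columns by number only, and the labels hold 2 numberings. One opens each sample title, and the other is the sequencing index at the end of each description. They give the same sample for 2 columns and different samples for 8. Columns were read by the sequencing index. That choice was made after marker genes had been looked at: Rag1, a recombinase gene of immature lymphocytes, reached at most 0.0391 CPM in columns 1 to 4 and at least 152 CPM in columns 5 to 10, whereas the titles place femoral cells in columns 1 to 4. If the title numbering is the right one, none of the comparisons holds. For the spleen samples, the titles and treatment fields also place SAHA on the opposite samples from the descriptions. The description was used, as fixed before the data were examined.

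Genes were tested in R 4.3.3 with edgeR 4.0.16 on the deposited counts: filterByExpr (minimum count 10), TMM factors, quasi-likelihood F tests and Benjamini-Hochberg adjustment over all genes tested. A gene is called at an adjusted p of 0.05. Every adjusted p of a gene is from this test unless an alternative is named beside it. The 4 spleen libraries formed one fit (2 residual degrees of freedom) and the 6 femoral libraries another (3), with no covariate. The 9 immunoglobulin sums add the counts of all segments of a class, were tested in the same fit and were adjusted over the 9 sums. Levels are CPM, the counts scaled by TMM-adjusted library size, as mean ± SD with n = 2, and log2 fold changes carry ± SE. With 2 libraries against 2, an exact permutation test cannot give a p below 0.333, and 33.3% of genes separate the groups by chance.

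The 25 gene lists were fixed before the data were examined and tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the lists of a comparison. Lists with fewer than 3 tested members were left out of the test. An estimated correlation and fry, which asks whether a list's genes move one way without comparing them with other genes, were run beside it. Named genes followed a rule fixed at the same time. It takes the 8 called genes with the largest change in each direction whose libraries do not overlap, with at least 5 CPM in the higher group and without predicted names or V, D and J segments. It adds the 2 members of each tested list with the smallest adjusted p, and 13 fixed genes, with 8 IgH constant genes, Rag1, Rag2, Prdm1 and Tmem121 among them. Not every gene it added is given in the text, and 1 fixed gene and 1 gene added from a list are left out in every comparison. Fold changes against a group with no counts are bounds at 3 counts per library. Ratios resting on 1 to 3 counts carry 95% counting intervals, which cover counting error only.

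The pipeline was tested on simulated counts with known fold changes. Each gene was drawn separately from its measured spread, so no shift shared by many genes of a library was simulated. Recovery of 4-fold changes was 67.3% in the spleen design (13913 genes) and 76.7%, 82.7% and 76.3% in the comparisons of 2KO with deltaEmu, 2KO with RAG2_deficient and deltaEmu with RAG2_deficient (16538 genes). Recovery of 2-fold changes was 7%, 28%, 28.3% and 25.3% in the same order. Over 3 simulations each, 19 of 242, 16 of 330, 24 of 357 and 22 of 327 calls were false, above the 5% aimed at in 3 of the 4 designs. Camera found the raised list in all 3 simulations of each design. It also found the unchanged list in 1 of 3 for 2KO against deltaEmu and in 0 of 3 for the others. Because the simulated genes varied independently, this does not test camera on lists whose members vary together. Alternatives were other scalings, other low-count filters, removal of immunoglobulin, mitochondrial and ribosomal RNA genes, all 10 libraries in one fit, a test against a 1.5-fold change, DESeq2 1.42.0, each library left out in turn and, in the spleen, the pool number as a block. The reading by title number, a crossed pairing of the pools and counts without immunoglobulin, Y-linked and Xist genes were added after the data had been seen. Total counts ran from 17710154 to 25544275, so 3 counts correspond to 0.117 to 0.169 CPM per library. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom from 41 to 276), so none was a repeated deposit.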

Results

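RNA levels were measured in cells labelled femoral (bone marrow) B cells, of 3 genotypes, and in cultured splenic B cells with and without SAHA, in 2 libraries per group. The series asks how deletion of 2 enhancers, and SAHA, affect transcription of the immunoglobulin heavy chain locus (IgH). The femoral groups carry the names 2KO, deltaEmu and RAG2_deficient. The labels do not spell out 2KO, while the design text names mice deficient for the IgH enhancer Eµ and the 3′ regulatory region, and no wild-type femoral group was analysed here. Mice were 8 to 10 weeks old. Total counts were 20039308 and 20825349 in 2KO, 19606981 and 17710154 in deltaEmu, 17950487 and 17890591 in RAG2_deficient, 24231004 and 20198437 in LPS_IL4, and 24794863 and 25544275 in LPS_IL4_SAHA.

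Each count column was assigned by the sequencing index in its sample's description, a choice made after marker genes had been seen, and the titles would assign 8 of the columns differently. With the index, Rag1 lay at 152 to 1060 CPM in the 6 femoral libraries and at 0 to 0.0391 CPM in the 4 spleen libraries. Rag2, the gene named in the RAG2_deficient label, had 20.4 and 27.5 CPM there, against 14.1 to 21.1 CPM in the other femoral libraries. The labels do not say which part of Rag2 is deleted, so a count over the whole gene checks nothing. The 6 femoral libraries also held RNA of other marrow lineages, with summed levels of 6720 to 20800 CPM for 10 neutrophil markers, 2570 to 16700 CPM for 10 erythroid markers and 1320 to 8330 CPM for 8 stromal markers, against 973 to 2340 CPM for 10 pro-B genes and 919 to 1610 CPM for 20 mature B cell genes. The IgH constant genes lie on the reverse strand of chromosome 12 (mm10), from Ighm at 113418558 to 113422730 down to Igha at 113254830 to 113260236.

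The first femoral comparison, 2KO against deltaEmu, bears on the series' question about the enhancer deletions. By the group names, the comparisons with RAG2_deficient differ in Rag2 as well as in the enhancers. Effects of Rag2 and of the enhancers cannot be told apart there. Levels in whole libraries of mixed cells cannot tell IgH transcription per cell from the share of cells that express immunoglobulin genes. Immunoglobulin transcripts were low in 2KO and abundant in deltaEmu. Summed over all IgH V, D, J and constant segments, 2KO held 22.6 ± 3.64 CPM and deltaEmu 1690 ± 161 CPM (log2 -6.23 ± 0.31, 74.8-fold lower in 2KO, adjusted p = 1.6e-07). Ighm, which encodes the constant region of IgM, was 99.2-fold lower, at 5.30 ± 1.14 against 527 ± 69.0 CPM (adjusted p = 9.06e-05). The kappa light chain constant gene Igkc, on chromosome 6, was 142-fold lower (4.58 ± 1.28 against 652 ± 44.0 CPM, adjusted p = 6.7e-05). Erythroid genes went the other way, and 9 of 10 rose in 2KO, although with an estimated correlation the list was not called (camera adjusted p = 0.222).

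The loss covered every IgH class. All 8 tested IgH constant genes fell in 2KO, also when adjusted over the list alone, and the list median was -9.45, or -5.80 with 6 members set at their bounds or ratios (camera adjusted p = 6.73e-81, and adjusted p = 0.00657 with an estimated correlation). Igha, the IgA constant gene, held 717 ± 3.98 CPM in deltaEmu and 0.0494 ± 0.0699 CPM in 2KO, a ratio of 6.64e-05 with a counting interval of 8.04e-06 to 0.00024. No count was found in 2KO for Ighg1 (35.7 ± 3.80 CPM in deltaEmu, at least 250-fold lower), Ighg2c (at least 39.8-fold), Ighd (at least 35.3-fold), Ighg3 (at least 29-fold) or Ighe (at least 5.77-fold). Ighg2b was 78-fold lower. The IgH V sum was 16.8 ± 4.58 against 369 ± 90.6 CPM (21.9-fold lower, adjusted p = 1.36e-06) and the IgH J sum 0.0971 ± 0.0724 against 2.29 ± 0.62 CPM (adjusted p = 0.000127). The IgH D sum, at 0.0247 ± 0.0349 against 0.405 ± 0.432 CPM (adjusted p = 0.0194), rested on 1 count in 2KO, and its adjusted p became 0.0698 without 2KO replicate 3 and 0.223 without deltaEmu replicate 7. The kappa V sum was 178-fold lower, the kappa J sum 6.06-fold lower and the lambda sum 29.5-fold lower, with adjusted p of 1.66e-07, 0.000127 and 4.79e-07. Tmem121, downstream of the locus, differed by -0.03 ± 0.45 (adjusted p = 0.986), and none of the 13 tested IgH neighbours was called.

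**Figure D1:**
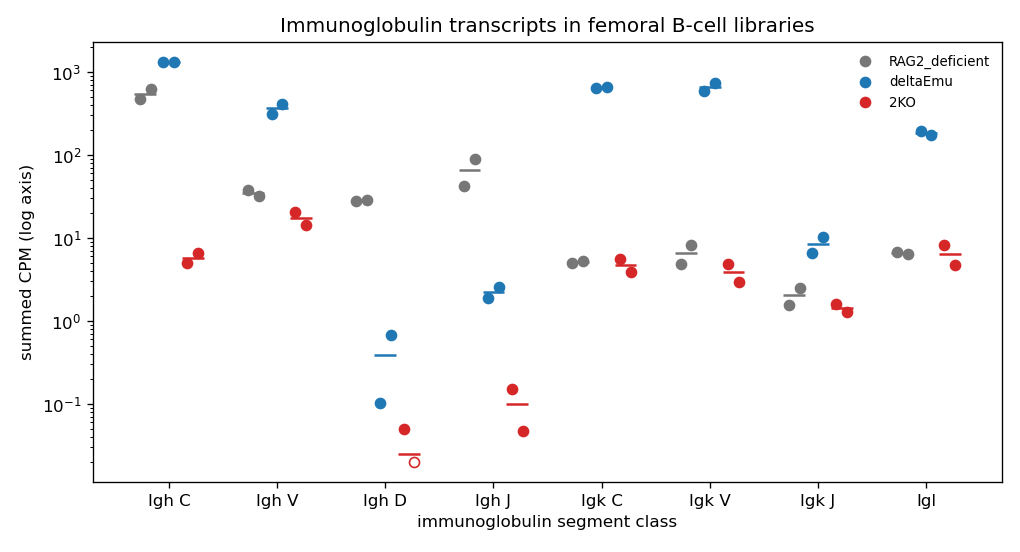
Summed CPM (log axis) of each immunoglobulin segment class in the 6 femoral libraries, with 1 point per library and a line at the group mean; the open circle stands for a library with a sum of 0, drawn at 0.02. The deltaEmu points lie above the 2KO points in all 8 classes, and the RAG2_deficient points lie above both in IgH D and J.

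The mature B cell, plasma cell and pre-B lists were called as lower in 2KO by camera. Of 20 mature B cell genes, 6 fell and none rose, or 14 fell when adjusted over the list alone (median -0.85, camera adjusted p = 3.37e-16, and adjusted p = 0.222 with an estimated correlation). They included Ms4a1, which encodes CD20 (0.286 ± 0.0149 against 20.4 ± 4.87 CPM), and the complement receptor gene Cr2 (0.0477 ± 0.00249 against 4.33 ± 0.33 CPM, a ratio of 0.011 with an interval of 0.00133 to 0.0406). Of 18 plasma cell genes, 3 fell, or 6 fell and 1 rose when adjusted over the list alone (median -0.40, camera adjusted p = 4.06e-08, and adjusted p = 0.222 with an estimated correlation): Jchain, the joining chain of IgA and IgM, was at 0.0477 ± 0.00249 against 503 ± 86.5 CPM (a ratio of 9.56e-05, 1.16e-05 to 0.000345), and Irf4, a transcription factor, was 2.15-fold lower. Of 9 pre-B cell genes, 2 fell (Cd2, log2 -1.83 ± 0.32, and Irf4), or 3 when adjusted over the list alone (camera adjusted p = 0.0188, and adjusted p = 0.363 with an estimated correlation). The pre-B list had an adjusted p of 0.086 without 2KO replicate 3 and 0.0637 without deltaEmu replicate 7.

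The pro-B, recombination and early B transcription factor lists were not called. Rag1, of the V(D)J recombinase, was at 207 ± 86.9 CPM in 2KO and 190 ± 47.9 CPM in deltaEmu (log2 0.12 ± 0.34, adjusted p = 0.915), and Dntt, the terminal transferase gene, at 191 ± 54.9 and 239 ± 44.6 CPM (adjusted p = 0.629). No member was called among 10 pro-B genes (camera adjusted p = 0.437), 11 recombination genes (0.934) or 11 early B transcription factors (0.934), nor over each list alone, although the pro-B list reached 0.042 without 2KO replicate 1.

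Markers of other marrow lineages moved beside the immunoglobulin genes. Among 10 erythroid markers 9 rose, or all 10 when adjusted over the list alone (median 2.31, camera adjusted p = 4.8e-22, and adjusted p = 0.222 with an estimated correlation). Slc4a1, the red cell anion exchanger, was 8.64-fold higher in 2KO (1111 ± 528 against 128.5 ± 28.7 CPM) and the alpha globin gene Hba-a2 5.03-fold higher. None of 10 neutrophil markers was called, although 6 fell when adjusted over the list alone (median -0.87, camera adjusted p = 2.5e-05, and adjusted p = 0.211 with an estimated correlation). Among 8 stromal markers Dcn alone fell (log2 -1.07 ± 0.17; over the list alone 4 fell and 1 rose), and among 12 Bcl2 family genes Bcl2l1 alone rose (1.19 ± 0.25). The interferon list was not called (adjusted p = 0.548) but reached 0.000652 without 2KO replicate 3 and 0.000567 without deltaEmu replicate 7. The stromal and receptor signalling lists (0.062 and 0.0753) reached 0.0199 and 0.0284 with all libraries when immunoglobulin, mitochondrial and ribosomal RNA genes were left out, 0.014 and 0.0196 without 2KO replicate 1, and 0.0265 and 0.0331 without deltaEmu replicate 5. The proliferation list (0.0753, median 0.20) reached 0.0491, 0.0489, 0.0486 and 0.0265 without RAG2_deficient replicates 1 and 2, 2KO replicate 1 and deltaEmu replicate 5, and the ribosome biogenesis list (0.0753) 0.0265 without deltaEmu replicate 5.

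Of 16538 genes tested, 612 were called, 296 higher and 316 lower in 2KO. The lower ones included 122 immunoglobulin genes. The 8 largest increases by the rule for named genes were Trim12a, Trim5, Hist1h4m, Ly6c1, Klri2, Redrum, Hmgb1-ps8 and RP23-412J12.1. Trim12a, of a family of antiviral factors, was at 34.2 ± 12.1 against 0.025 ± 0.0353 CPM, and Ly6c1, a surface antigen of myeloid and other blood cells, at 40.6 ± 0.0308 against 0.505 ± 0.291 CPM. Trim12a and Trim5 were at 76.55 ± 17.9 and 22.7 ± 1.71 CPM in RAG2_deficient, where Klri2, Redrum and Hmgb1-ps8 were also present. For these genes deltaEmu was the group apart. Ly6c1, Hist1h4m and RP23-412J12.1 were low in RAG2_deficient as in deltaEmu. The interferon-inducible gene Ifi202b was at least 561-fold lower in 2KO (no count, against 80.2 ± 15.4 CPM), and Iglc2, a lambda constant gene, 108-fold lower. In RAG2_deficient Ifi202b was at 0.0258 ± 0.0364 CPM. Hist1h4m, a histone gene, and the pseudogene Hmgb1-ps8 have near-identical copies that reads may be shared with. The other 18 lists were not called (camera adjusted p 0.062 to 0.934), and median, mean and test differed in sign for the IgH neighbours, histone deacetylases, recombination genes, early B factors and plasmacytoid markers. The neuronal list was not tested for want of expressed members.

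The count of 612 became 378 (233 higher, 145 lower) when immunoglobulin, mitochondrial and ribosomal RNA genes were removed beforehand, and 1572, 1587, 249, 147 and 119 without RAG2_deficient replicate 1, RAG2_deficient replicate 2, 2KO replicate 3, deltaEmu replicate 5 and deltaEmu replicate 7. Of 28 named genes that were called, 8 were not called without deltaEmu replicate 7, 7 of the 27 still tested without deltaEmu replicate 5, 5 without 2KO replicate 3 and 3 without 2KO replicate 1, with adjusted p of 0.0517 to 0.365. They were Slc4a1 (0.11 without deltaEmu replicate 7), Hba-a2 (0.0755), Irf4, Cd2, Dcn, Bcl2l1, Ighe and Redrum.

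Compared with RAG2_deficient, the 2KO libraries again held less IgH RNA. The IgH sum was 22.6 ± 3.64 against 679 ± 49.9 CPM (log2 -4.91 ± 0.29, 30-fold lower, adjusted p = 6.17e-07). The difference lay in Ighm (100-fold lower, 533 ± 31.3 CPM in RAG2_deficient), in the D sum (0.0247 ± 0.0349 against 28.8 ± 3.25 CPM, with 1 count in 2KO) and in the J segments (0.0971 ± 0.0724 against 64.7 ± 24.8 CPM, 636-fold lower). The D sum of RAG2_deficient came almost wholly from the segment Ighd4-1, with 501 of 501 and 514 of 515 counts in its libraries. Light chain RNA was low in both groups: the kappa constant gene was at 4.58 ± 1.28 and 5.24 ± 0.492 CPM (adjusted p = 0.519) and the lambda sum at 6.33 ± 2.52 and 6.76 ± 1.25 CPM (adjusted p = 0.747).

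Of 8 IgH constant genes, 3 fell, over all genes and over the list alone (median -2.41, camera adjusted p = 1.01e-09, and adjusted p = 0.162 with an estimated correlation): Ighm, Ighd (at least 97.7-fold) and Ighg2b (8.54-fold). Ighg1 and Ighe had no count in either group. The list median rests on Ighg3 and Ighg2c (log2 -2.41 and -2.40), with 1 count each in RAG2_deficient and 0 in 2KO. It is therefore no measured shift of the list. The IgH V sum was 2.14-fold lower in 2KO (adjusted p = 0.00992), but its adjusted p was 0.0953 without 2KO replicate 3. The kappa V sum was 3.77 ± 1.38 against 6.51 ± 1.65 CPM (adjusted p = 0.0633), with an adjusted p of 0.0275 without RAG2_deficient replicate 1 and 0.0304 without 2KO replicate 1. Adam6b, which lies between the V and D segments, was at least 16.6-fold lower, the one neighbour called of 13.

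The pro-B, recombination and early B transcription factor lists were also called as lower in 2KO by camera. Of 10 pro-B genes 4 fell, or 7 over the list alone (median -1.26, camera adjusted p = 2.3e-06, and adjusted p = 0.371 with an estimated correlation), including Igll1, a part of the surrogate light chain (107 ± 34.3 against 423 ± 18.5 CPM), and Dntt (191 ± 54.9 against 566 ± 38.3 CPM). Of 11 recombination genes 3 fell, or 4 over the list alone (camera adjusted p = 0.00132, and adjusted p = 0.371 with an estimated correlation): Rag1 (207 ± 86.9 against 874 ± 146 CPM), Dntt and Xrcc6. Of 11 early B transcription factors 3 fell, or 6 over the list alone (camera adjusted p = 0.000936, and adjusted p = 0.371 with an estimated correlation), among them Pax5 (log2 -1.49 ± 0.31) and Bach2 (-1.39 ± 0.30). The mature B cell list was split: 4 members rose, including Cd74 and the class II transactivator gene Ciita (log2 1.17 ± 0.16), and 4 fell, with 5 and 5 over the list alone (camera adjusted p = 0.38). Single members fell in lists that were not called: Cd79b (log2 -1.24) in receptor signalling, Enpep (-1.91) in the pre-B list, Slamf7 (-1.26) in the plasma cell list, Hdac11 (-2.13) among deacetylases and Xrcc6 (-1.08) in the class switch list.

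Stromal markers fell most among the other lineages. Of 8 markers 6 fell, or all 8 over the list alone (median -2.48, camera adjusted p = 1.26e-27, and adjusted p = 0.162 with an estimated correlation), such as the collagen-binding Dcn (8.91 ± 1.10 against 66.1 ± 1.19 CPM) and Lum (8.86-fold lower). Of the 8 largest decreases, Col10a1, a collagen, was 14-fold lower, the bone matrix gene Bglap2 13.3-fold, Cthrc1 21.7-fold, Sema3d 14-fold, Pcdh9 12.6-fold and Prss35 11.8-fold, beside Ighd and Ighm. Of 10 erythroid markers 4 rose, or all 10 over the list alone (median 1.30, camera adjusted p = 1.36e-10, and adjusted p = 0.371 with an estimated correlation), such as Alas2, a heme synthesis enzyme (3.14-fold). Of 9 NK markers Klrb1c alone fell (log2 -2.03 ± 0.22), or 2 over the list alone (median -0.49, camera adjusted p = 0.0187, and adjusted p = 0.479 with an estimated correlation). None of 10 neutrophil markers was called, over all genes or over the list alone (median 0.47, camera adjusted p = 0.0187, and adjusted p = 0.371 with an estimated correlation). The NK call ended without RAG2_deficient replicate 2 (adjusted p = 0.0735) and without 2KO replicate 3 (0.197), and the neutrophil call without 2KO replicate 1 (0.0854). The monocyte gene Cd14 was 4.16-fold higher, the T cell gene Cd3e at least 3.66-fold higher and the platelet gene Ppbp 6.22-fold lower.

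The ribosome biogenesis and proliferation lists were called as higher in 2KO by camera and by neither other list test. The ribosome biogenesis list had 2 of 12 members called, over all genes and over the list alone, Odc1 of polyamine synthesis (2.17-fold) and Cad of pyrimidine synthesis (1.71-fold), with a camera adjusted p of 0.00414 (adjusted p = 0.479 with an estimated correlation and 0.0819 with fry). The proliferation list had no member of 20 called, nor over the list alone (median 0.38, camera adjusted p = 0.00144, with adjusted p = 0.479 with an estimated correlation and 0.127 with fry).

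Of 16538 genes 713 were called, 208 higher and 505 lower in 2KO. The 8 largest increases held 4 genes of the Y chromosome, Eif2s3y, Kdm5d, Uty and Ddx3y (46.7 ± 1.90 against 0.124 ± 0.176 CPM), and otherwise Hist1h4m, Hist1h2al, Ifi44l and RP23-412J12.1. The Y-linked genes mark a difference in sex between these groups, which cannot be told apart from genotype. Xist, expressed from the inactive X chromosome and chosen after its values were seen, was at 928 ± 176 CPM in 2KO and 2073 ± 1200 CPM in RAG2_deficient (adjusted p = 0.181), and it was called as lower by DESeq2 (0.0307), without a low-count filter (0.00204) and without RAG2_deficient replicate 1 (0.0074). The other 14 lists were not called (camera adjusted p 0.0699 to 0.815), and mean and median differed in sign for the plasma cell and class switch lists. Of the lists not called, interferon response reached 0.00258 and T cell markers 0.0185 without 2KO replicate 3, B cell receptor signalling 0.0169 without 2KO replicate 1, and platelet and plasmacytoid markers 0.00143 and 0.00208 without RAG2_deficient replicate 2. The Bcl2 family reached 0.0311 without RAG2_deficient replicate 1, the pre-B list 0.0389 without 2KO replicate 1 and the platelet list 0.0493 without 2KO replicate 3.

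The count of 713 became 3222 without RAG2_deficient replicate 1, 345 and 153 without 2KO replicates 1 and 3, and 222 and 221 without deltaEmu replicates 5 and 7. Of 40 named genes that were called, 21 were not called without 2KO replicate 3, 19 and 18 without deltaEmu replicates 7 and 5, 11 without 2KO replicate 1 and 4 without RAG2_deficient replicate 2, with adjusted p of 0.0504 to 0.343. With all 10 libraries in one fit 7 were not called, with the stricter low-count filter 6 of the 38 still tested, and with library size alone 5, among them Pax5 (0.101, 0.053 and 0.0552), Bach2 (0.156, 0.0588 and 0.0727) and Cad (0.131, 0.0523 and 0.0945). Calls that ended without a library included Rag1 (0.162 without 2KO replicate 3), Dntt (0.23), Pax5 (0.284), Cd74 (0.121), Alas2 (0.158) and Adam6b (0.0917), while Ighm, Ighd, Lum and Dcn stayed called in each.

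**Figure D2:**
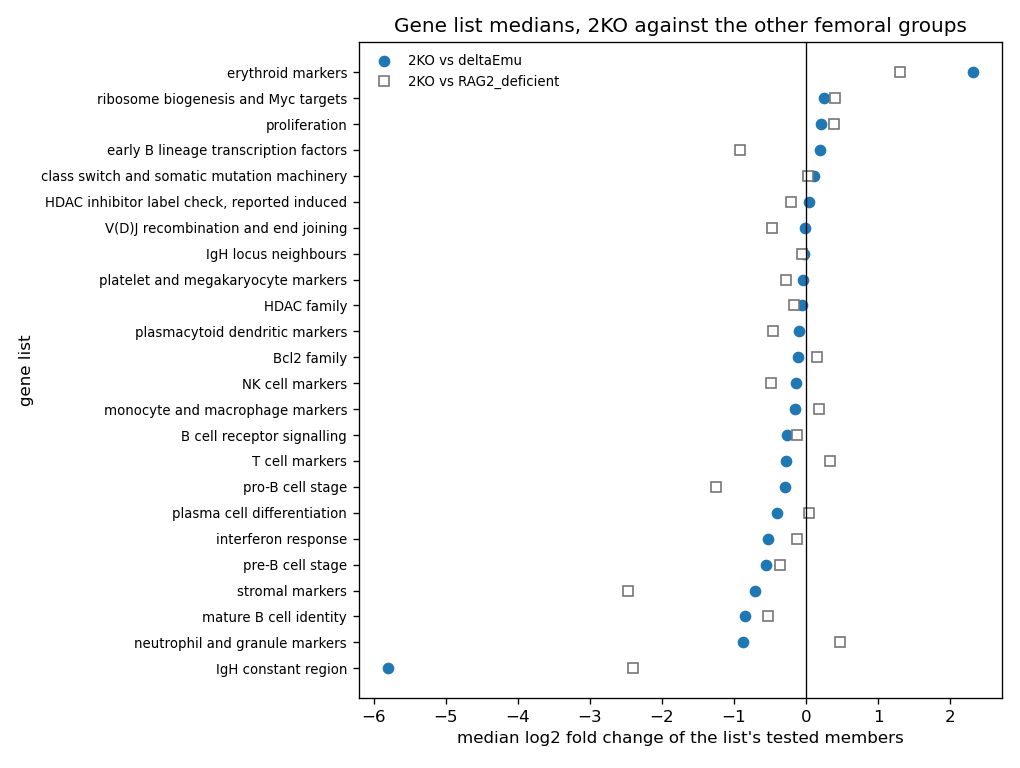
Median log2 fold change of the tested members of each of 24 gene lists, 2KO against deltaEmu (filled circles) and 2KO against RAG2_deficient (open squares), with members without counts in a group set at their bounds. Erythroid markers lie highest in both comparisons, at 2.31 and 1.30, and IgH constant genes lowest against deltaEmu, at -5.80.

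The deltaEmu libraries held more immunoglobulin RNA than RAG2_deficient, while Ighm was not called. The IgH sum was 1690 ± 161 against 679 ± 49.9 CPM (log2 1.32 ± 0.25, 2.49-fold, adjusted p = 0.000828), and Ighm was at 527 ± 69.0 and 533 ± 31.3 CPM (log2 -0.02 ± 0.23, adjusted p = 0.976). The higher RNA lay in switched classes and light chains: Igha at 717 ± 3.98 against 0.0258 ± 0.0364 CPM, Ighg1 at least 209-fold higher, Igkc 124-fold higher and the lambda sum 27.7-fold higher. The D and J sums were lower in deltaEmu, at 0.405 ± 0.432 against 28.8 ± 3.25 CPM and 2.29 ± 0.62 against 64.7 ± 24.8 CPM (adjusted p = 7.47e-06 and 2.81e-06). Almost all of the D sum of RAG2_deficient was the segment Ighd4-1. Counts per gene do not show whether IgH RNA came from rearranged loci. Like Ighm levels therefore need not mean like amounts of IgM RNA.

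Of 8 IgH constant genes 6 rose (median 6.95, or 5.21 with 5 members at their bounds or ratios; camera adjusted p = 1.06e-23, and adjusted p = 0.0417 with an estimated correlation), and over the list alone 6 rose and 1 fell. Ighd was at 5.05 ± 2.41 against 14.0 ± 6.48 CPM (adjusted p = 0.0955), and 0.013 without RAG2_deficient replicate 1. Ighg2b was 9.14-fold higher. Ighg2c and Ighg3, with 1 count each in RAG2_deficient, had ratios of 205 (36.4 to 8130) and 149 (26.4 to 5930), and Ighe was at least 4.84-fold higher. The IgH V sum was 10.3-fold, the kappa V sum 102-fold and the kappa J sum 4.19-fold higher, with adjusted p of 7.47e-06, 5.77e-07 and 0.000568. Adam6b fell by 4.09 on the log2 scale, the one neighbour called of 13.

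The mature B cell and plasma cell lists were called as higher in deltaEmu by camera. Of 20 mature B cell genes 10 rose and 2 fell, or 12 and 3 over the list alone (median 1.36, camera adjusted p = 1.41e-08, and adjusted p = 0.335 with an estimated correlation): Ms4a1 rose by 4.76 ± 0.43 and Ciita by 1.80 ± 0.17 on the log2 scale, while Ebf1, a factor of early B cells, changed by -1.97 ± 0.36. Of 18 plasma cell genes 5 rose and 1 fell, or 9 and 1 over the list alone (median 0.51, camera adjusted p = 3.17e-05, and adjusted p = 0.335 with an estimated correlation), with Jchain at 503 ± 86.5 against 0.388 ± 0.33 CPM and Derl3, of endoplasmic reticulum protein disposal, 6.16-fold higher. Cd2 rose (log2 1.47) while Enpep (-2.91) and Blnk (-1.08) fell in the pre-B list (camera adjusted p = 0.48), Blk rose and Blnk fell among receptor signalling genes (0.904), and Pmaip1, a Bcl2 family member, rose by 1.71.

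The pro-B, recombination and early B transcription factor lists were called as lower in deltaEmu by camera. Of 10 pro-B genes 4 fell, or 7 over the list alone (median -1.02, camera adjusted p = 0.00506), of 11 recombination genes 4, over all genes and over the list alone (-0.51, 0.00602), and of 11 early B transcription factors 4, or 5 fell and 1 rose over the list alone (-0.49, 0.00602). These lists had adjusted p of 0.463, 0.385 and 0.463 with an estimated correlation. The log2 change was -2.20 ± 0.35 for Rag1, -1.93 ± 0.31 for Igll1, -1.65 ± 0.31 for Foxo1, -1.30 ± 0.24 for Erg and -1.11 ± 0.24 for Lig4.

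All 8 stromal markers fell, also over the list alone (median -1.81, camera adjusted p = 3.23e-13; adjusted p = 0.327 with an estimated correlation), with Lum 5.05-fold lower. Of 10 neutrophil markers 5 rose, or all 10 over the list alone (median 1.36, camera adjusted p = 4.47e-08; adjusted p = 0.109 with an estimated correlation), including the granule genes Camp (759.5 ± 72.8 against 242 ± 42.9 CPM) and Elane. T cell markers were higher (4 rose, 1 fell, both also over the list alone, camera adjusted p = 0.0349) at low levels, with Cd3g at 2.71 ± 0.977 against 0.202 ± 0.0664 CPM and Trac at 1.17 ± 0.396 against 0.0568 ± 0.0075 CPM (a ratio of 21.2, 5.52 to 180), and erythroid markers were lower (1 fell, or 5 over the list alone, camera adjusted p = 0.00942). The T cell and erythroid lists had adjusted p of 0.335 and 0.625 with an estimated correlation. The T cell call ended without RAG2_deficient replicate 1 (0.158) and replicate 2 (0.145), and the erythroid call without RAG2_deficient replicate 1 (0.244). Of 10 monocyte markers 2 rose and 2 fell (0.382), with Cd14 7.74-fold higher and the complement gene C1qb 2.76-fold lower, and Klrb1c, Klrd1, Ccr9, Hdac11 and Hdac7 also fell.

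Of 16538 genes 1622 were called, 731 higher and 891 lower in deltaEmu, with 124 immunoglobulin genes among the higher. The largest increases included Eif2s3y, Kdm5d and Uty of the Y chromosome, Ifi202b (80.2 ± 15.4 against 0.0258 ± 0.0364 CPM) and Ifi44l. The Y-linked genes mark a difference in sex that comes with the genotype here. The largest decreases were Hmgb1-ps8, Trim12a, Eps8l1, A2m, Klri2, Trim5, Klra14-ps and Gvin1. The other 14 lists were not called (camera adjusted p 0.182 to 0.904), and mean and median differed in sign for receptor signalling. Among these, the interferon list reached 0.0472 without deltaEmu replicate 7, the NK list 0.0229 without deltaEmu replicate 5, the Bcl2 family 0.0371 without RAG2_deficient replicate 1 and plasmacytoid markers 0.0148 without RAG2_deficient replicate 2.

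The count of 1622 became 5401 without RAG2_deficient replicate 1, 259 without deltaEmu replicate 5 and 321 without deltaEmu replicate 7. Of 51 named genes that were called, 25 were not called without deltaEmu replicate 7, and 27 of the 50 still tested without deltaEmu replicate 5, with adjusted p of 0.0515 to 0.316, among them Rag1 (0.0659 and 0.132), Foxo1, Ebf1, Derl3, Camp, Elane, Cd14, Cd2, Erg, Lig4 and Trac. Without RAG2_deficient replicate 2 Adam6b (0.0765), Blnk, Blk and Ighe were not called, while Igha, Ighg1, Jchain, Ms4a1 and Lum stayed called in each.

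The spleen comparison asks whether SAHA changes IgH transcription in cultured B cells. No immunoglobulin gene or class sum was called between the libraries labelled SAHA and those without it. The IgH sum was 4065 ± 61.0 CPM in LPS_IL4_SAHA and 4604 ± 466 CPM in LPS_IL4 (log2 -0.18 ± 0.31, adjusted p = 0.806), and Ighm was at 3114 ± 41.9 and 3557 ± 224 CPM (log2 -0.19 ± 0.30, adjusted p = 0.939). Ighg1, a class to which IL4 directs switching, was at 12.3 ± 1.20 and 7.18 ± 2.46 CPM (log2 0.78 ± 0.30, adjusted p = 0.939). Prdm1, which encodes the plasma cell factor Blimp-1, was at 15.8 ± 1.19 and 34.0 ± 14.3 CPM (log2 -1.11 ± 0.33, adjusted p = 0.939), and without a low-count filter it was called (log2 -1.06, adjusted p = 0.035).

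No gene was called by edgeR among 13913 tested, with 187 genes at an unadjusted p under 0.05 where chance gives 696. DESeq2 also called 0 genes, with 264 at an unadjusted p under 0.05. The groups did not overlap for 24.8% of genes, against 33.3% by chance. The class sums were no clearer: the adjusted p was 0.806 for IgH C, J and V, kappa V and J, and lambda, 0.95 for IgH D and 0.993 for kappa C. The remaining IgH constant genes had log2 values of -0.15 (Ighg2b), 0.15 (Ighd), 0.18 (Ighg2c), 0.19 (Ighg3) and 0.23 (Igha).

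The plasma cell list was lower with SAHA by camera, with no member of 17 called over all genes or over the list alone (median -0.23, camera adjusted p = 0.0135). With an estimated correlation its adjusted p was 0.949, and it was 0.563 without LPS_IL4 replicate 4_et_7 and 0.298 without LPS_IL4_SAHA replicate 4_et_7. Its member Jchain was at 13.5 ± 2.18 and 23.3 ± 6.30 CPM. The mature B cell list had a median of 0.17 (camera adjusted p = 0.0947), with Cr2 at 183 ± 43.2 and 113 ± 8.22 CPM, and the early B transcription factors -0.55 (0.0947), with Bach2 at 52.1 ± 7.36 and 106 ± 75.4 CPM. Of the genes reported to be induced by histone deacetylase inhibitors none was called: the median of 7 was 0.10 (camera adjusted p = 0.936), and Cdkn1a was at 2.91 ± 0.159 and 4.92 ± 0.14 CPM. The titles and treatment fields place SAHA on the other 2 libraries, which would reverse each sign with SAHA, and these genes do not decide between the labels. Proliferation genes had a median of 0.06 (0.587), with Mki67 at 540 ± 287 and 801 ± 496 CPM, interferon response -0.29 (0.22), the Bcl2 family 0.12 (0.376), ribosome biogenesis 0.04 (0.541), histone deacetylases 0.07 (0.862), class switch genes -0.01 (0.862), receptor signalling -0.01 (0.835), IgH constant genes 0.18 (0.327) and IgH neighbours 0 (0.936). The pre-B, pro-B, recombination, monocyte and plasmacytoid lists had camera adjusted p of 0.688, 0.936, 0.936, 0.936 and 0.936, and none of the members of any list was called, over all genes or over the list alone. Median, mean and test differed in sign for the IgH neighbours, class switch, deacetylase, induced, pro-B, recombination, receptor signalling and plasmacytoid lists. The other 7 lists had too few expressed members to test, with summed levels in the 4 libraries of at most 5 CPM for erythroid, 4.82 for T cell, 2.43 for NK, 2.43 for platelet, 1.2 for neuronal, 0.446 for neutrophil and 0.149 for stromal markers.

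The count of 0 became 145 without a low-count filter, 2670 (1085 higher, 1585 lower) without LPS_IL4 replicate 4_et_7 and 5 without LPS_IL4 replicate 6_et_8, a library in which the RNA Gm26917 took 4.48% of counts against 0.536% to 1.27% in the others. Without LPS_IL4 replicate 4_et_7, the SAHA libraries are set against LPS_IL4 replicate 6_et_8 alone, which stood apart from the other spleen libraries. Differences of that library cannot then be told apart from effects of SAHA. Log2 values were -1.445 for Prdm1, 1.205 for Ighg1, -1.582 for Bach2, 0.808 for Cr2 and -1.06 for Mki67. For the IgH J and lambda sums they were -0.755 and 0.798. Without LPS_IL4 replicate 6_et_8, Mki67 and both sums changed sign (0.272, 0.184 and -0.124), and Jchain had a log2 value of -1.02.

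**Figure D3:**
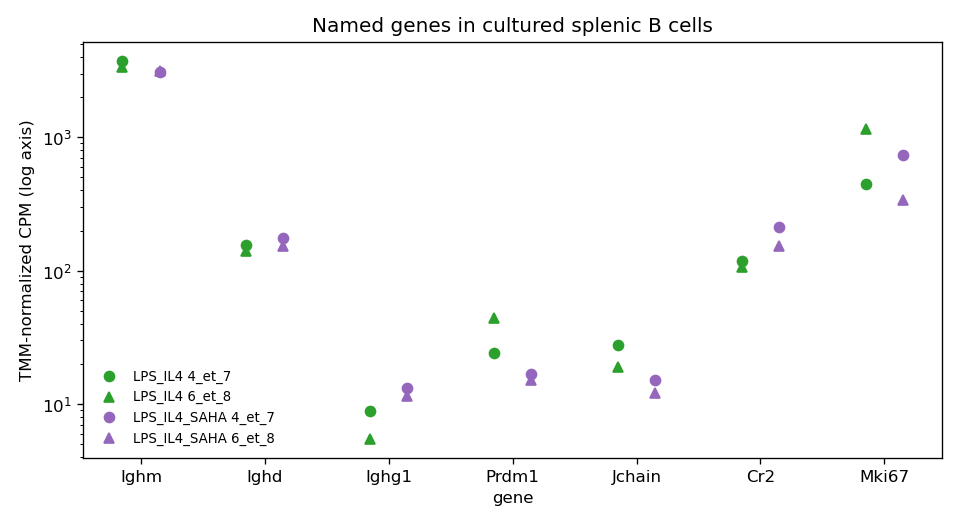
Levels of 7 genes in the 4 spleen libraries in TMM-scaled CPM (log axis), with color for treatment and marker shape for pool. Prdm1 lies lower and Ighg1 higher in both libraries labelled SAHA, yet no gene was called, and the LPS_IL4 pools lie apart for Prdm1 and Mki67.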

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

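No test in this part was chosen after results were seen. Within a group of 2 libraries, neither can be told to be the outlying one, so no such search was made in this part. LPS_IL4 replicate 6_et_8, which stood apart from all other spleen libraries, is taken up under the other observations. Counts for the phiX174 genome, a sequencing control whose entry no comparison uses, lay above 3, the limit that a count of 0 allows, in 4 of the 10 libraries. They were 17 in LPS_IL4_SAHA replicate 6_et_8, 7 in RAG2_deficient replicate 1, 5 in LPS_IL4 replicate 4_et_7 and 4 in 2KO replicate 1. No explanation was tested.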

How the results depend on the processing

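The reading of columns by title number, the crossed pairing of pools and the counts without immunoglobulin, Y-linked and Xist genes were chosen after the data had been seen, and the other alternatives before the data were examined. The summed IgH RNA kept its direction and its side of the threshold under each alternative run on it, with log2 values over the left-out libraries of -6.39 to -6.07 for 2KO against deltaEmu, -5.07 to -4.74 for 2KO against RAG2_deficient, 1.22 to 1.42 for deltaEmu against RAG2_deficient and -0.263 to -0.039 with SAHA. Leaving out a library leaves its group with 1 library, which is assumed to vary like the other groups. Gene counts depended on the libraries and on the test. Without a library they ranged from 119 to 1587 for 2KO against deltaEmu, from 153 to 3222 for 2KO against RAG2_deficient, from 259 to 5401 for deltaEmu against RAG2_deficient and from 0 to 2670 with SAHA. In that order, no low-count filter gave 1537, 1971, 3308 and 145 (1 higher, 144 lower) genes. A test against a 1.5-fold change gave 359, 267, 797 and 0, and DESeq2 949, 1242, 2064 and 0. Removal of immunoglobulin, mitochondrial and ribosomal RNA genes before the fit gave 378 for 2KO against deltaEmu, where 122 of the called genes are immunoglobulin genes. Without immunoglobulin, Y-linked and Xist genes in the count there were 490, 687 and 1484 calls in the femoral comparisons. Columns read by title number gave 0, 8101, 8721 and 0 genes in the same order (186 and 85 genes at an unadjusted p under 0.05 where 0 were called by edgeR), since 2KO and deltaEmu would then hold the columns in which Rag1 had at most 0.0391 CPM. With the pool number as a replicate block 0 genes were called with SAHA (104 at an unadjusted p under 0.05), and with crossed pools as the block 0 (1279).

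Of the called named genes, library size alone ended 1 of 28, 5 of 40 and 1 of 51 calls for 2KO against deltaEmu, 2KO against RAG2_deficient and deltaEmu against RAG2_deficient, the stricter low-count filter 1 of 27, 6 of 38 and 2 of 47, all 10 libraries in one fit 0 of 28, 7 of 40 and 2 of 51, RLE factors 0 of 28, 0 of 40 and 1 of 51, and removal of immunoglobulin, mitochondrial and ribosomal RNA genes 1 of 18, 1 of 37 and 1 of 45. They were Irf4 and Bcl2l1 for 2KO against deltaEmu (adjusted p 0.055 to 0.0583), Pax5, Bach2, Xrcc6, Cad, Odc1, Cd79b, Cd14, Ppbp and Hba-a2 for 2KO against RAG2_deficient (0.0509 to 0.156) and included Blk and Hdac7 for deltaEmu against RAG2_deficient (0.0568 and 0.0779). For 2KO against deltaEmu the stromal and receptor signalling lists were called once immunoglobulin, mitochondrial and ribosomal RNA genes were left out (adjusted p 0.0199 and 0.0284), and for 2KO against RAG2_deficient the platelet list with library size alone (0.0351). Without a low-count filter Prdm1 was called with SAHA (log2 -1.06, adjusted p = 0.035).

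Of the lists called, 5 of 6, 10 of 10, 9 of 10 and 1 of 1 were not called with an estimated correlation, and 2, 6, 3 and 1 not with fry. Fry, unlike camera with all libraries, called the class switch list for 2KO against deltaEmu (0.026) and deltaEmu against RAG2_deficient (0.015), the deacetylase family for 2KO and deltaEmu against RAG2_deficient (0.0475 and 0.0261) and T cell markers for 2KO against RAG2_deficient (0.0475). Of all results there were 100 changes of sign over 53 results, in 0 of which a called value was involved, and the cause was not tested. The kappa C sum with SAHA had a log2 value of 0.001 with RLE factors, 0.029 without a low-count filter, 0.001 with DESeq2, 0.037 with all 10 libraries in one fit and 0.02 with the replicate block. For 2KO against deltaEmu, Tmem121 and Rag2 had log2 values of 0.03 and 0.049 with library size alone, and for deltaEmu against RAG2_deficient Tmem121 and Ighm had 0.016 and 0.025 with all 10 libraries in one fit. Lists changed direction at adjusted p of 0.995 (pro-B, SAHA), 0.974 (plasmacytoid, 2KO against deltaEmu) and 0.937 (receptor signalling, deltaEmu against RAG2_deficient) with library size alone. With immunoglobulin, mitochondrial and ribosomal RNA genes left out, the deacetylase family and early B factor lists did so at 0.986 for 2KO against deltaEmu, and with fry at 0.994. With fry and SAHA, the IgH neighbours did so at 0.969 and the deacetylase inhibitor label check, recombination and plasmacytoid lists at 0.982.

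Leaving out single libraries gave these lowest and highest values for results whose sign changed. Log2 values with SAHA were Adgre1 -0.066 to 0.941, Cad -0.747 to 0.041, Igh D sum -0.375 to 0.346, Igh J sum -0.755 to 0.184, Igh V sum -0.457 to 0.143, Igha -0.125 to 0.738, Ighg2c -0.062 to 0.507, Igk C sum -0.223 to 0.314, Igk J sum -0.42 to 0.12, Igk V sum -0.258 to 0.055, Igl sum -0.124 to 0.798, Il2ra -1.188 to 0.131, Mki67 -1.199 to 0.272, Prkdc -0.857 to 0.14 and Runx1 -1.31 to 0.034. For 2KO against deltaEmu they were Ifit3 -2.575 to 0.085, Rag1 -0.381 to 0.499, Rag2 -0.342 to 0.321 and Tmem121 -0.289 to 0.235, for 2KO against RAG2_deficient Igha -2.383 to 3.043, Igk C sum -0.496 to 0.076, Igl sum -0.554 to 0.275 and Tmem121 -0.306 to 0.242 and for deltaEmu against RAG2_deficient Ighm -0.146 to 0.121, Prdm1 -0.193 to 0.485 and Tmem121 -0.284 to 0.268. Adjusted p of lists with SAHA were early B factors 0.0313 to 0.874, deacetylase inhibitor label check 0.516 to 0.758, IgH neighbours 0.555 to 0.836, monocyte 0.00242 to 0.92, plasmacytoid 0.173 to 0.986, pro-B 0.513 to 0.617, proliferation 0.396 to 0.965 and recombination 0.309 to 0.876. For 2KO against deltaEmu they were early B factors 0.642 to 0.928, deacetylase family 0.871 to 0.955, deacetylase inhibitor label check 0.642 to 0.969, interferon 0.000567 to 0.596, NK 0.157 to 0.777, plasmacytoid 0.752 to 0.905, pro-B 0.042 to 0.917 and recombination 0.61 to 0.871. For 2KO against RAG2_deficient they were class switch 0.738 to 0.981, deacetylase inhibitor label check 0.0878 to 0.967, IgH neighbours 0.466 to 0.967, interferon 0.00258 to 0.741, monocyte 0.125 to 0.734 and plasma cell 0.277 to 0.97. For deltaEmu against RAG2_deficient they were receptor signalling 0.771 to 0.992, deacetylase inhibitor label check 0.118 to 0.862, interferon 0.0472 to 0.899, monocyte 0.099 to 0.923 and platelet 0.216 to 0.771.

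Depth limits what can be said of rare transcripts. A count of 0 in a library allows 0.117 to 0.169 CPM, so differences between groups that both lie under this level, such as Igha, Ighg2c and Ighg3 in 2KO and RAG2_deficient, were not detectable at this depth. In simulations 7% of 2-fold changes were recovered in the spleen comparison and 25.3% to 28.3% in the femoral ones.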

Other observations

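The tests of the column numberings, of strain segments, of shared reads and of one library apart were chosen only after results were seen, as were the genes named in this part. The tests of exchanged labels, of neighbouring genes and of the spread were planned before.

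Of 5 heat shock genes looked at, Hspa1a and Hspa1b were called as higher in deltaEmu than in either other femoral group. Hspa1a and Hspa1b, which encode inducible chaperones of the Hsp70 family, were at 297.6 ± 0.905 and 304.7 ± 18.1 CPM in deltaEmu, at 6.91 ± 4.84 and 9.18 ± 5.97 CPM in 2KO and at 1.16 ± 0.91 and 2.22 ± 0.731 CPM in RAG2_deficient. Both were called between deltaEmu and 2KO (adjusted p = 0.00241 and 0.00139) and between deltaEmu and RAG2_deficient (0.000641 and 0.000353). The chaperone genes Hsph1 and Dnajb1 were 2.92-fold and 2.04-fold higher in deltaEmu than in RAG2_deficient (adjusted p = 0.0152 and 0.0143). They were not called between deltaEmu and 2KO (0.114 and 0.0633), and Hspa8, a constitutive member of the family, was called in neither comparison (0.183 and 0.209). Hspa1a and Hspa1b kept their calls under each alternative run on single genes. Against RAG2_deficient Hsph1 and Dnajb1 lost theirs without deltaEmu replicate 5 (adjusted p = 0.132 and 0.121) and without deltaEmu replicate 7 (0.0834 and 0.118). Against 2KO both and Hspa8 were called without either RAG2_deficient library (0.00571 to 0.0427), by DESeq2 (0.00175 to 0.026) and without a low-count filter (0.000222 to 0.0453).

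Sex-linked genes differed too. Ddx3y, on the Y chromosome, lay at 47.4 to 48.5 CPM in 2KO, 50.3 to 71.7 CPM in deltaEmu and at most 0.223 CPM in RAG2_deficient, while Xist, on the X chromosome, lay at 701 to 3170 CPM in all 6 femoral libraries. In the spleen libraries Xist was at most 0.206 CPM and Ddx3y 43.2 to 120 CPM. The labels give no sex. By these genes, RAG2_deficient held next to no RNA of males, whereas the 2KO and deltaEmu libraries did hold it. In both comparisons with RAG2_deficient, sex thus differed along with genotype and cannot be told apart from it.

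The first pattern is the pair of column numberings. If columns followed the number that opens each title, femoral cells would lie in columns 1 to 4, where Rag1 reached at most 0.0391 CPM against at least 152 CPM elsewhere, which argues against that numbering. With the sequencing index, 6 of 6 femoral libraries correlated best with the other library of their group, which is consistent with the index numbering, a hypothesis found on the same values. Of the 4 spleen libraries 0 did so, with r = 0.9715 between LPS_IL4 replicate 6_et_8 and LPS_IL4_SAHA replicate 4_et_7 against 0.9609 between the LPS_IL4 libraries, and over genes the difference between pools correlated at -0.442 between libraries with and without SAHA. An exchange of columns within the spleen stays open, and so does a full exchange of the SAHA labels, which titles and treatment fields give and which would reverse each sign with SAHA and leave its adjusted p.

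The second pattern is the count of 0 genes called with SAHA by edgeR, with 187 at an unadjusted p under 0.05 and 0 by DESeq2. Simulations that drew each gene separately from the measured spread recovered 67.3% of 4-fold and 7% of 2-fold changes. They held no shift shared by many genes of a library, so they do not decide whether the spread hides 4-fold changes here. Smaller effects stay open. LPS_IL4 replicate 6_et_8 stood apart from the other spleen libraries (r = 0.9545 to 0.9715, against 0.9874 to 0.9919 among those). Without it fewer genes were called than a sole cause would predict, with 87.3% of simulated 4-fold and 41.3% of 2-fold changes recovered. That fit leaves LPS_IL4 with 1 library and rests on the same simulations, so LPS_IL4 replicate 6_et_8 as the sole cause is not excluded. Labels exchanged within one pool cannot be told apart from the labels as given, because that split also gave 0 genes (1568 at an unadjusted p under 0.05, and 54 for pool against pool). The bound of 10 genes written before that test was wrong, since few 2-fold changes can be recovered in this design, and an absent effect of SAHA stays open as well.

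The third pattern is a set of 59 called genes, outside the immunoglobulin genes and Jchain, with a log2 difference of at least 4 between 2KO and deltaEmu and at least 1 CPM in the higher group, 43 higher in 2KO and 16 in deltaEmu, over 18 chromosomes. Some of the 43, such as Trim12a, Gvin1 and Gm1966, were present in RAG2_deficient too, so that deltaEmu was the group apart. Others of the 43, such as Ly6c1 and Gm13394, were low in RAG2_deficient. With 0 of the 59 within 5 Mb of the IgH constant genes, where 62 genes were tested, the positions argue against an effect on neighbouring genes as the cause of this set. Random sets had a median of 0 and an upper limit of 1, so the count could not have fallen below chance. It does not address weaker effects of the deleted enhancers on neighbours. Of these 59, 11 lie within 500 kb of another one that does not overlap it and whose symbol opens with other letters. In 1000 random sets of like expression the median was 2 and the upper limit 8. Segments of another mouse strain are a candidate explanation for part of the set. Symbols that open differently can still belong to related genes, such as Gvin1 and Gm1966. The count therefore cannot tell strain segments from clusters of related genes. The limit to non-overlapping pairs was set after a first count of 15 had been seen. Reads shared between near-identical copies may explain another part, since 25.4% are annotated as pseudogenes (median of the random sets 6.8%, upper limit 13.6%), which decides nothing for the other genes. Marker lists of cell types differed between 2KO and deltaEmu by camera, with erythroid genes higher (adjusted p = 4.8e-22) and mature B cell genes lower (3.37e-16). With an estimated correlation neither list was called (adjusted p = 0.222 for each). Whether cell types explain the set stays open and was not tested, and 4 of the 59 are in the mature B cell list.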
